A study of Mus musculus with 16 samples.

How the data were processed

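Osteoclasts were grown from CD11b-positive bone marrow cells of C57BL/6J mice, per the labels' protocols: 3 days in M-CSF at 50 ng/ml, then RANKL at 20 ng/ml was added, and RNA was taken when the first mature osteoclasts appeared, on day 3 to 5. The day of each culture is not given in the sources used here. Libraries were made from 500 ng of RNA with poly(A) selection, a strand-specific kit and adaptors carrying unique molecular identifiers (UMIs), per the labels' protocols. The 16 libraries fall into 4 genotypes with 4 replicates each. The design text states a larger total of samples than these groups add up to, and the labels mention a FLT3 inhibitor that no sample is labelled with.

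The authors deposited a table of raw counts, whole numbers per gene without normalization. Tools named per the submitters' processing notes were bcl2fastq 2.20.0.422, cutadapt 4.2, STAR 2.7.6a, UMI-tools 1.1.1 and featureCounts 2.0.3, on build GRCm38.p6, and neither their order, their settings nor the use of strand is given in the sources used here. A second deposited table holds TPM, counts scaled to gene length and library total, from the authors, scaled to the same sum in each library. The TPM values imply 1.67 to 1.74 reads per deposited count, whole within 0.1 for 100% of the genes checked and never fewer than the count, so this table was not made from the deposited counts. Gene positions came from the GENCODE annotation of the same build, in which 21894 of the deposited gene IDs were found.

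The counts were tested with edgeR 4.0.16 in R 4.3.3: genes kept by filterByExpr (12093), TMM factors, and a robust quasi-likelihood fit of the 4 group means over all 16 libraries, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The comparisons were the 5 pairs of groups that differ in FLT3, in Ptprc or in both from WT, and the interaction. CPM, counts scaled to the library total, use TMM-scaled library sizes, and log2 CPM a prior count of 2. The standard error of a log2 fold change was taken from the fold change and its F statistic. Gene lists, 18 for pathways and 14 for cell types, were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 32 lists of a comparison. List scores are means of log2 CPM over the measured members, compared by exact permutation, for which 4 against 4 libraries cannot give a p under 0.0286.

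Total counts per library were 24211724 to 35773313, and the common dispersion was 0.137 (a coefficient of variation of 0.37 between replicates), with 12 residual degrees of freedom. For genes with 0 counts over a group, folds were taken against 3 counts over the group, and for those with 1 to 3 counts the ratio is given with an exact 95% binomial interval. Intervals and floors cover counting error only.

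The design, the lists and the naming rule were fixed before the data were examined. Named genes were Ptprc and Flt3. For each pair of groups came up to 10 rises and 10 falls with the largest change among genes past the threshold, with a mean of at least 5 CPM and library ranges that did not overlap. Predicted gene models and Y-linked genes were left out. The interaction took up to 5 each way without the condition on overlap, and members of the fixed lists could also be named.

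Alternatives were RLE factors, no filter, a mean count of at least 50, a replicate block, a fit of only the groups compared, DESeq2 1.42.0, voom with quality weights, limma on log2(TPM + 1) for genes with a mean TPM of at least 1, an estimated correlation and fry for the lists, and each library left out in turn. Added after seeing the data were the close FLT3 ITD libraries summed, the length-dependent library left out as well, removal of the length trend, 1 surrogate variable (sva 3.50.0), the reads implied by the TPM table, and exact permutation of the lists.

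The scripts were tested on simulated counts with 200 changed genes per comparison. For FLT3 ITD against WT (12000 genes tested), edgeR recovered 42.4% of 2-fold, 85.1% of 4-fold and 97% of 8-fold changes, with 4 false among 154 calls. For Ptprc KO against WT (12015 genes), the shares were 50%, 86.6% and 95.5%, with 10 false among 165 calls. For the double mutant against FLT3 ITD (12014 genes), they were 53%, 83.6% and 89.6%, with 9 false among 160 calls. For the double mutant against Ptprc KO (12014 genes), they were 51.5%, 85.1% and 89.6%, with 6 false among 157 calls. For the double mutant against WT (11992 genes), they were 39.4%, 86.6% and 94%, with 3 false among 150 calls. The changed genes had a mean count of at least 50, and all genes were drawn independently, with no library that stood apart from its group. The real libraries differ in this, so the recovered shares and false calls hold for the simulated counts only. In the same simulations camera called 0 to 1 of 50 unchanged lists per comparison, but those simulated genes were drawn independently, whereas real genes of a list move together, so the preset correlation is the lenient choice for the lists.

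For the closing section, every split of the 8 libraries of a pair of groups into 4 and 4 (35 splits), or 100 drawn splits for the interaction and the correlations, was fitted as the real groups were, and for the correlations with 1 common dispersion for all genes. Added after seeing the data were counts without Ptprc for Ptprc KO and the double mutant against WT, and the 35 splits of 7 libraries for FLT3 ITD against WT with replicates 1 and 3 summed. Libraries far from the other 3 of their group were found with Dixon's ratio over 0.829. Relations between scores used deviations from group means over the 16 libraries, with p from permutation of these 16 deviations, which are not fully exchangeable because those of a group sum to 0. Genes chosen after their values were seen are named as such where they occur.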

Results

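RNA was sequenced from 16 osteoclast cultures, grown from CD11b-positive bone marrow cells of C57BL/6J mice with M-CSF and RANKL, the cytokines that drive osteoclast formation. The cultures fell into 4 groups of 4: wild type (WT), a knockout of Ptprc (Ptprc KO), a knock-in of the internal tandem duplication of Flt3 (FLT3 ITD), and both changes together (FLT3 ITD Ptprc KO, here the double mutant). Ptprc encodes CD45, a receptor tyrosine phosphatase of blood cells, and FLT3 ITD is a constitutively active receptor tyrosine kinase found in acute myeloid leukaemia. Total counts per library ranged from 24211724 to 35773313, and 12093 genes had enough counts to be tested. The design asks what each change does to osteoclast expression and whether the effect of one depends on the other. The labels do not say that the replicates came from separate animals, so the p-values measure the spread between these cultures.

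Ptprc (ENSMUSG00000026395; GRCm38 chromosome 1, 138062861 to 138175708) was measured first, in every library. It stood at 454 ± 28.5 CPM (SD, n = 4; CPM are counts scaled to the library total) in WT, at 472, 412, 464 and 469 CPM in replicates 1 to 4. In the Ptprc KO libraries it stood at 38.7 ± 6.45 CPM (SD, n = 4), at 41.5, 36.6, 30.8 and 45.8 CPM. FLT3 ITD libraries held 401 ± 129 CPM (SD, n = 4), at 416, 230, 414 and 543 CPM, and double-mutant libraries 64.8 ± 15.3 CPM (SD, n = 4), at 54.1, 86.7, 63.8 and 54.5 CPM. All 8 libraries labelled as knockouts lay under all 8 others, and 816 to 2507 counts of the gene remained in each of them. The remaining level was 8.51% of WT in Ptprc KO and 16.2% of FLT3 ITD in the double mutant. Flt3 (chromosome 5) was near the limit of detection, with 1 to 41 counts per library, and the duplication itself cannot be read from gene counts.

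**Figure D1:**
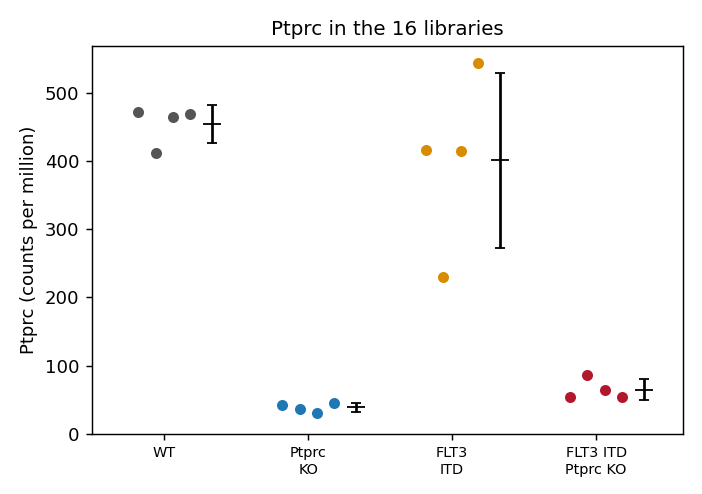
Ptprc in CPM for each of the 16 libraries, by group; points are libraries, and the black mark with its bar is the mean and SD of 4. The 8 knockout libraries lie between 30.8 and 86.7 CPM and the others between 230 and 543 CPM.

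Osteoclast gene levels differed widely between cultures of the same genotype. The mean log2 CPM of 16 genes of the resorption machinery, the acid and protease system that dissolves bone, was 9.88 ± 0.15 in WT and 10.14 ± 0.68 in Ptprc KO (SD, n = 4). It was 10.12 ± 0.82 in FLT3 ITD and 8.72 ± 0.91 in the double mutant (SD, n = 4). FLT3 ITD replicate 4 stood apart from its group at 8.89, and double-mutant replicate 3 stood apart from its group at 10.06. The first principal component of the 1000 most variable genes held 57.4% of their variance, of which 26.1% lay between groups. FLT3 ITD replicates 1 and 3 had counts far closer than any other pair of libraries (chi-square per gene 2.76, against 13 for the next closest pair). FLT3 ITD replicate 2 had values that trended with gene length (Spearman rho -0.46 across genes, which are not independent replicates, against -0.181 to 0.181 in the other libraries).

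**Figure D2:**
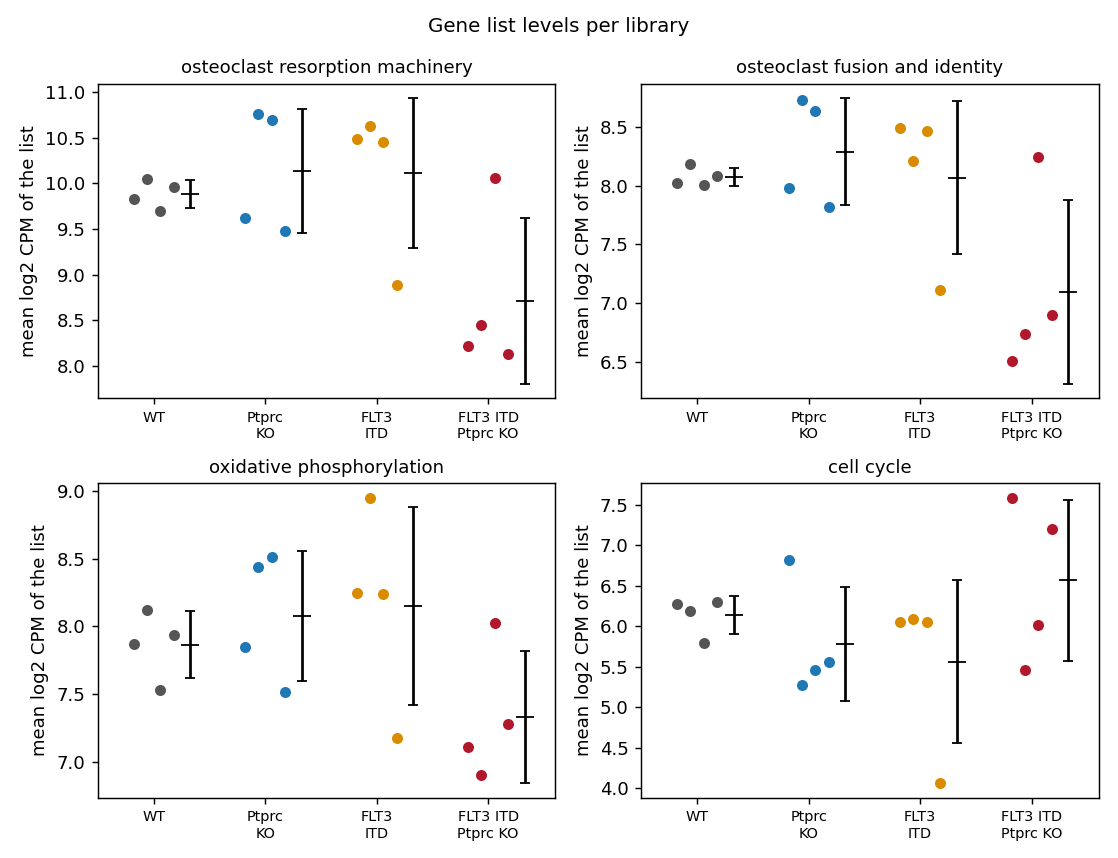
Mean log2 CPM of 4 gene lists in each library, by group; points are libraries, and the black mark with its bar is the mean and SD of 4. For the resorption list, 3 double-mutant libraries lie between 8.13 and 8.45 and the remaining double-mutant library at 10.06.

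FLT3 ITD against WT asks what the receptor mutation does where Ptprc is intact. Wdfy1, which encodes an endosomal FYVE-domain protein, rose from 42.9 ± 5.71 to 175 ± 38.6 CPM (SD, n = 4 and 4). Its log2 fold change was 2.03 (SE 0.28, adjusted p = 0.021, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment; chromosome 1, 79702262 to 79776143). Lzts2, a leucine zipper protein gene, rose from 8.19 ± 1.89 to 24.6 ± 5.89 CPM (SD, n = 4 and 4), a log2 fold change of 1.58 (SE 0.25, adjusted p = 0.044; chromosome 19, 45014414 to 45027111). Vsig4, a complement receptor gene of tissue macrophages, had 32 to 150 counts in each WT library and 0 counts in all 4 FLT3 ITD libraries. It was at least 111-fold lower, taken against 3 counts over the group (adjusted p = 0.044). Cdh13, encoding T-cadherin, rose (log2 fold change 4.96, SE 0.6, adjusted p = 0.0092), from 0.0769 to 2.45 CPM on average, and Paqr9 fell (log2 fold change -4.15, SE 0.66, adjusted p = 0.044). Vsig4, Cdh13 and Paqr9 lay under the level set for named genes and were chosen after their values were seen. Whether the near-identical FLT3 ITD replicates 1 and 3 are separate cultures is not given in the sources used here. With them summed into 1 library, Cdh13 kept its call and the other 4 genes lost theirs, and with replicate 2 left out as well edgeR called 0 genes (381 at an unadjusted p under 0.05; DESeq2 called 64 with all libraries).

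In the same comparison, all 16 resorption genes had positive log2 fold changes (median 0.35) without passing as a list (camera adjusted p = 0.22), and Ctsk, the main bone-degrading protease, stood at 0.52 (SE 0.6). Of the 5 lists that passed with the preset correlation, none did with an estimated one (adjusted p = 0.58 for the erythroid list and 0.8 for the others). Oxidative phosphorylation lay higher (24 of 24 genes positive, median log2 fold change 0.46, camera adjusted p = 0.011), as did glycolysis and hypoxia genes (16 of 17 positive, median 0.29, adjusted p = 0.023). The highest oxidative phosphorylation score of all libraries was that of FLT3 ITD replicate 2, whose values trended with gene length (8.949, against 8.248, 8.235 and 7.174 in replicates 1, 3 and 4). With TPM the median of the list was 0.08, where that of all genes was -0.21. Cell cycle genes lay lower (22 of 24 negative, median -0.35, adjusted p = 0.0085). Only FLT3 ITD replicate 4 had a low cell cycle score, at 4.058. Replicates 1 to 3, at 6.052, 6.09 and 6.057, lay within the WT range of 5.79 to 6.3. Markers of stromal and osteoblast-lineage cells also lay lower (7 of 8 measured genes negative, median -2.41, adjusted p = 0.0085), among them Col1a1 at -3.06 (SE 1.29) and Sparc at -2.46 (SE 1.11). Col1a1 was low, at 0.83, 6.39, 2.58 and 16.7 CPM in WT replicates 1 to 4. In FLT3 ITD it stood at 0.345, 0.39, 0.375 and 2.08 CPM. WT replicates 1 and 3 had stromal scores of -0.556 and 0.559, within the FLT3 ITD range of -1.38 to 0.58. With TPM the stromal median was -0.43. No member of these 4 lists passed over all genes or adjusted over the list alone. The erythroid list held only Epor, the erythropoietin receptor, with 75 counts over the WT group and 1 over FLT3 ITD (adjusted p = 0.04). Among progenitor markers, Cd34 rose (log2 fold change 2.15, SE 0.47, 0.0025 adjusted over the list alone) and so did Gata2 (1.9, SE 0.63, 0.028 adjusted over the list alone), while the other 4 measured members did not pass. Timd4 and Ear2, outside the called lists as well, fell adjusted over their lists alone. In all, 5 genes passed (3 rose and 2 fell), with 1022 at an unadjusted p under 0.05 where uniform p-values would give 605. Uniform p-values are assumed for this reference, so 605 is not a measure of what chance gives in these libraries. Leaving out each library in turn kept Cdh13 in 6 of 8 fits and each of the other 4 genes in 1 of 8. Wdfy1 overlaps Mrpl44 on the other strand (log2 fold change 0.3, SE 0.24), and Lzts2 overlaps Pdzd7, and the use of strand in counting is not given in the sources used here, so both are uncertain to that extent.

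Ptprc KO against WT asks what the loss of CD45 does where Flt3 is normal. Besides Ptprc itself (log2 fold change -3.55, SE 0.25, adjusted p = 7e-06, edgeR quasi-likelihood test; lower in 4 of 4 libraries), 3 genes changed. Stard13 rose from 0.332 ± 0.069 to 5.62 ± 4.66 CPM (SD, n = 4 and 4; log2 fold change 4.06, SE 0.53, adjusted p = 0.007), and is uncertain because 1 annotated protein-coding gene overlaps it on the same strand. Rbm44, an RNA-binding protein gene, had 86 counts over the WT group and 1 over the knockout group, a ratio of 76.7 (95% counting interval 13.4 to 3070; adjusted p = 0.007). Glrp1 had 248 counts and 1 count, a ratio of 221 (95% counting interval 39.4 to 8780; adjusted p = 0.022). These 3 genes lay under the level set for named genes and were chosen after their values were seen. Of the 100 genes with the lowest p besides Ptprc, 25 lay on chromosome 1, which carries Ptprc, Rbm44 and Glrp1 and 6% of the tested genes.

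Among the lists of this comparison, 8 passed with the preset correlation and none of their members passed over all genes or adjusted over the list alone. With an estimated correlation none of the 8 passed (adjusted p = 0.26 for the stromal list, 0.77 for the mast cell list and 0.93 for the other 6). Resorption genes lay higher (16 of 16 positive, median log2 fold change 0.38, camera adjusted p = 0.015), with Ctsk at 0.42 (SE 0.6) and Acp5 at 0.36 (SE 0.55). The same held for fusion and identity genes (18 of 19, median 0.2, adjusted p = 0.043) and oxidative phosphorylation (24 of 24, median 0.25, adjusted p = 0.00064). The rise did not hold in every knockout library. Resorption scores were 10.759 and 10.695 in Ptprc KO replicates 2 and 3, over the WT range of 9.7 to 10.05. In replicates 1 and 4 they were 9.618 and 9.48, under that range. Fusion and identity scores split the same way (8.729 and 8.632 against 7.977 and 7.82, with WT at 8.01 to 8.18). Cell cycle genes lay lower (24 of 24 negative, median -0.24, adjusted p = 0.00078), as did cholesterol biosynthesis (14 of 15, median -0.29, adjusted p = 0.02). Stromal and osteoblast-lineage markers lay lower (7 of 8, median -2.1, adjusted p = 4.7e-08), and neutrophil markers (9 of 10, median 0.89, adjusted p = 0.015) and mast cell and basophil markers (2 of 2, median 0.86, adjusted p = 0.02) higher. The last 2 were Kit and Gata2, the only measured members, which are also on the progenitor list. Col1a1, a stromal marker, was low, at 0.83, 6.39, 2.58 and 16.7 CPM in WT replicates 1 to 4. In Ptprc KO it stood at 1.02, 0.219, 0 and 3.07 CPM. WT replicates 1 and 3 had stromal scores of -0.556 and 0.559, within the Ptprc KO range of -1.94 to 0.74. With TPM the stromal median was -0.38, where that of all genes was -0.08. In all, 4 genes passed, with 102 at an unadjusted p under 0.05 where uniform p-values would give 605. The 102 lie under that reference, so the p-values of this comparison were not uniform. Ptprc and Rbm44 kept their call in 8 of 8 fits with 1 library left out, Stard13 in 7 and Glrp1 in 2.

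**Figure D3:**
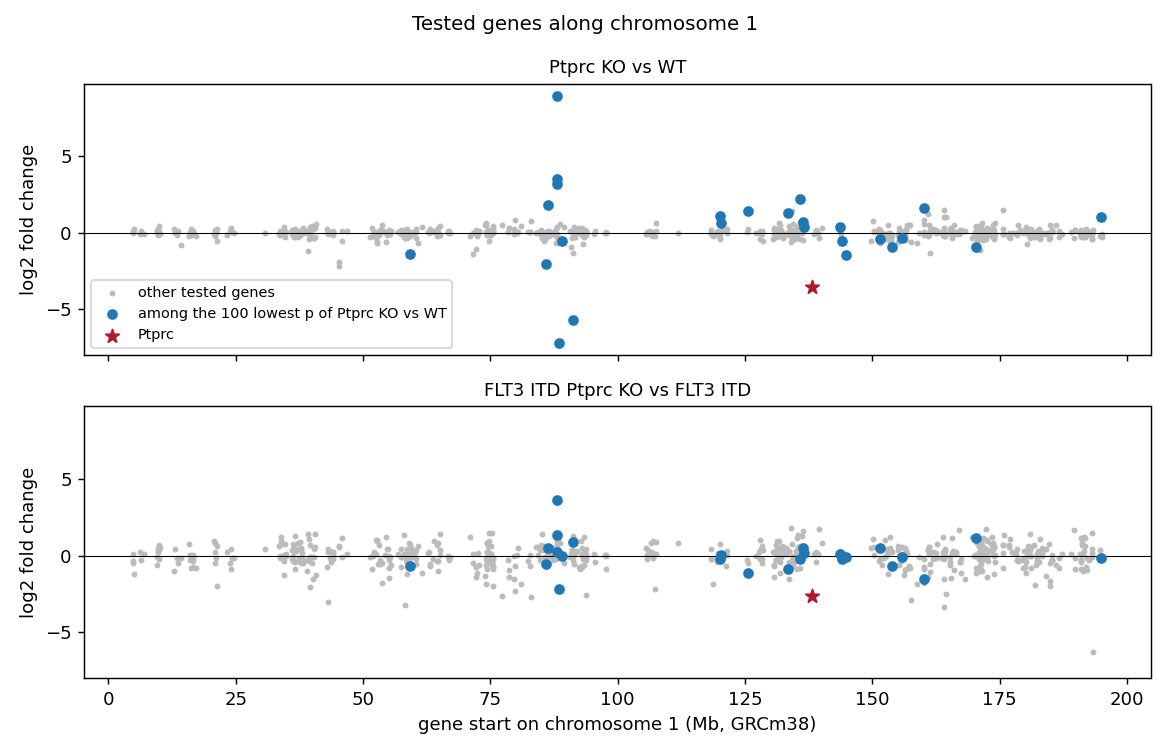
Log2 fold change of each tested gene on chromosome 1 against its start in Mb, for the Ptprc KO against WT (top) and the double mutant against FLT3 ITD (bottom). Blue points are the 25 chromosome 1 genes among the 100 with the lowest p in the first comparison, and the star is Ptprc, at -3.55 and -2.63.

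The double mutant against FLT3 ITD asks what the loss of CD45 does in cells that carry the mutant receptor. Genes of the resorption machinery stood lower in all 16 members (median log2 fold change -1.04, camera adjusted p = 1.3e-07 with the preset correlation). With an estimated correlation the adjusted p was 0.87 for this and the other 5 lists that passed with the preset one. Of the resorption genes, 7 fell adjusted over the list alone, among them Ctsk (-1.85, SE 0.62), Car2, the carbonic anhydrase that supplies acid (-1.95, SE 0.66), and Acp5, the tartrate-resistant phosphatase (-1.54, SE 0.57; n = 4 and 4). Fusion and identity genes stood lower in 18 of 19 members (median -0.67, adjusted p = 0.00023), and 4 fell adjusted over the list alone, including the calcitonin receptor Calcr (-2.3, SE 0.57) and the integrin Itgb3 (-1.64, SE 0.48). The master regulator of the lineage, Nfatc1, stood at -0.23 (SE 0.51) and did not pass. Oxidative phosphorylation stood lower in 24 of 24 genes (median -0.9, adjusted p = 1.1e-07), and 18 fell adjusted over the list alone, such as Ndufa4 (-1.43, SE 0.46) and Cox4i1 (-0.98, SE 0.31). FLT3 ITD replicate 2, the library with the length trend, held the highest score of its group for this list (8.949). With TPM the median of the list was -0.63, where that of all genes was 0.22.

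In the opposite direction, cell cycle genes stood higher in 24 of 24 members (median 0.97, adjusted p = 8.3e-05), with Top2a at 1.46 (SE 0.64), and none passed adjusted over the list alone. Cell cycle scores were 7.591 and 7.207 in double-mutant replicates 1 and 4. In its replicates 2 and 3 they were 5.458 and 6.023, under FLT3 ITD replicates 1 to 3 (6.05 to 6.09). FLT3 ITD replicate 4 stood apart from its group at 4.06. Interferon response genes stood higher in 20 of 20 (median 0.56, adjusted p = 0.0013) and Src-family kinases and CD45 partners in 10 of 12 (median 0.48, adjusted p = 0.031), with Fyn at 0.9 (SE 0.38) and none passing adjusted over the list alone in either list. Outside the called lists, Nos2, the inducible nitric oxide synthase, rose (4.14, SE 0.74, 0.00084 adjusted over the list alone), as did the T cell costimulator Cd80 (1.1, SE 0.25, 0.0063 adjusted over the list alone) and the receptor phosphatase Ptprs (0.97, SE 0.21, 0.0058 adjusted over the list alone). These were 1 of 15 inflammatory, 1 of 11 MHC class II and, with Ptpro, 2 of 14 phosphatase genes. Nos2 was near the floor in FLT3 ITD, at 0.219, 0.13, 0.0625 and 0.333 CPM in replicates 1 to 4. Double-mutant replicates 1 to 4 held 3.06, 0.865, 6.81 and 2.55 CPM of it, so the size of its fold is uncertain. With 1 endothelial marker, 5 genes outside the called lists rose adjusted over the list alone. That way 5 fell: the only measured mast cell and basophil markers Kit and Gata2, 1 STAT5 target, 1 coupling factor and 1 eosinophil marker. Kit and Gata2 are also on the progenitor list. Over all 12093 genes only Ptprc passed (log2 fold change -2.63, SE 0.24, adjusted p = 0.00023, edgeR quasi-likelihood test, lower in 4 of 4 libraries), while 3104 genes had an unadjusted p under 0.05 where uniform p-values would give 605. The exact permutation test of the resorption score gave p = 0.0571 (two-sided, 4 against 4 libraries, smallest possible p 0.0286). Without FLT3 ITD replicate 4, 1798 genes passed, and without double-mutant replicate 3, 1315 genes passed.

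The double mutant against Ptprc KO asks what the receptor mutation does in cells without CD45. The neighbouring genes Tfpi2 and Gng11, on chromosome 6 from 3962595 to 3988919 and from 4003904 to 4008445, both fell. Tfpi2, a serine protease inhibitor gene, went from 10.6 ± 4.78 to 0.713 ± 0.521 CPM (SD, n = 4 and 4; log2 fold change -3.89, SE 0.52, adjusted p = 0.0092, edgeR quasi-likelihood test). Gng11, a G protein gamma subunit gene, went from 14.6 ± 4.53 to 1.25 ± 0.655 CPM (SD, n = 4 and 4; -3.54, SE 0.48, adjusted p = 0.0092). Trip6, a LIM-domain protein gene on chromosome 5 (137309654 to 137314404), fell from 20.5 to 4.43 CPM (-2.2, SE 0.32, adjusted p = 0.011), where WT stood at 6.8 and FLT3 ITD at 8.28 CPM, so that the Ptprc KO level was the high one. Gdf3, a ligand gene of the TGF-beta superfamily on chromosome 6 (122605403 to 122610087), fell from 15.9 to 0.486 CPM (-5.03, SE 0.87, adjusted p = 0.045). Lipo3, a lipase gene on chromosome 19 (33555160 to 33761951), fell from 32.3 to 14.5 CPM (-1.15, SE 0.19, adjusted p = 0.039), and is uncertain because 6 annotated genes, Lipo2 among them, overlap it on the same strand.

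Under the level set for named genes, 6 further genes were chosen after their values were seen. Vsig4 had 0 counts in the double mutant and was at least 122-fold lower, taken against 3 counts over the group. Dysf, the membrane repair gene dysferlin, had 168 counts over the knockout group and 1 over the double mutant, a ratio of 191 (95% counting interval 33.8 to 7580). Paqr9 (log2 fold change -5.57, SE 0.7) and Epha4 (-4.12, SE 0.66) fell, and Clec2f (5.46, SE 0.76) and Rbm44 (91 counts against 1, a ratio of 80.1, 95% counting interval 14 to 3200) rose. For Rbm44 the Ptprc KO level was the low one (0.0109 CPM, against 0.682 in WT and 0.718 in the double mutant). Clec2f belongs to a family of close copies and is uncertain.

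Resorption genes stood lower in 16 of 16 members here too (median -1.15, camera adjusted p = 4.3e-09 with the preset correlation). With an estimated correlation the adjusted p was 0.66 for this and the other 6 lists that passed with the preset one. Of the resorption genes, 11 fell adjusted over the list alone, with Ctsk at -1.75 (SE 0.62). Fusion and identity genes stood lower in 17 of 19 (median -0.98, adjusted p = 8.7e-07), and 2 fell adjusted over the list alone, Calcr (-3.28, SE 0.59) and Itgb3 (-1.61, SE 0.48). Oxidative phosphorylation stood lower in 24 of 24 (median -0.66, adjusted p = 7.4e-08) and cell cycle genes higher in 24 of 24 (median 0.93, adjusted p = 0.00046), with none passing adjusted over the list alone. Genes of MHC class II presentation stood higher in 11 of 11 (median 1.62, adjusted p = 0.00062), and 3 rose adjusted over the list alone: Cd80 (1.22, SE 0.25), the class II transactivator Ciita (1.82, SE 0.44) and H2-DMb1 (1.08, SE 0.33). Inflammatory cytokine genes stood higher in 13 of 15 (median 1.17, adjusted p = 0.029), with Nos2 passing adjusted over the list alone. Nos2 was low in Ptprc KO too, at 0.227 to 0.692 CPM. Glycolysis and hypoxia genes stood higher in 14 of 17 (median 0.46, adjusted p = 0.039), with none passing adjusted over the list alone. Of STAT5 target genes, a list that did not pass, Socs2, a cytokine feedback inhibitor gene, fell (-2.5, SE 0.44, 0.00068 adjusted over the list alone). It was 1 of 9 genes outside the called lists that fell that way, and 6 rose. Neutrophil markers (8 of 10 negative, median -2.68, adjusted p = 0.058), granulocyte progenitor markers (4 of 4 negative, median -2.76, adjusted p = 0.07) and eosinophil markers (2 of 3 negative, median -3, adjusted p = 0.11) did not pass as lists. In all, 11 genes passed (2 rose and 9 fell), with 2155 at an unadjusted p under 0.05 where uniform p-values would give 605. With 1 library left out, Rbm44 and Paqr9 kept their call in 8 of 8 fits, Tfpi2 in 7, Gng11, Clec2f and Dysf in 6, Trip6 in 5, Epha4 and Vsig4 in 3, and Lipo3 and Gdf3 in 1. Without double-mutant replicate 3, 786 genes passed.

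**Figure D4:**
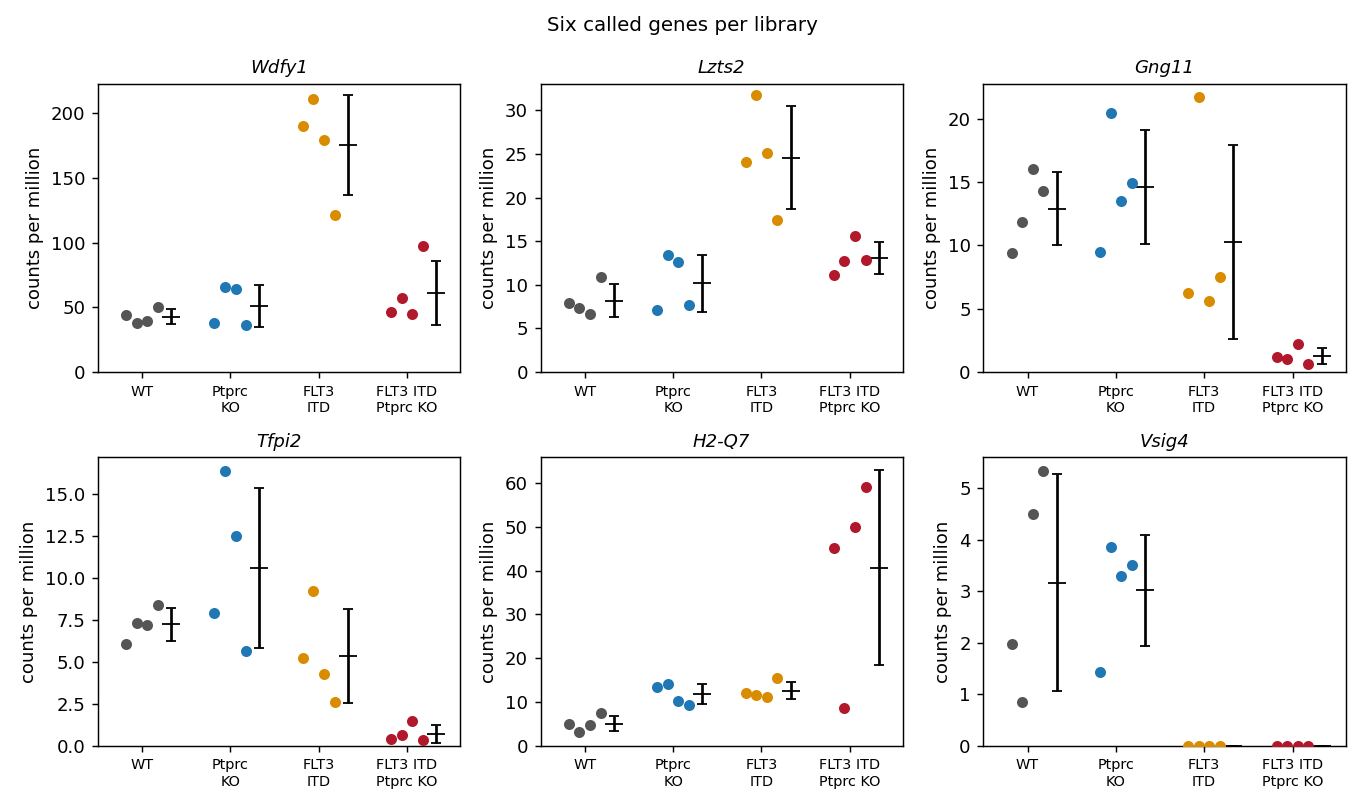
CPM of Wdfy1, Lzts2, Gng11, Tfpi2, H2-Q7 and Vsig4 in each library, by group; points are libraries, and the black mark with its bar is the mean and SD of 4. Vsig4 is at 0 in the 8 libraries with FLT3 ITD, and H2-Q7 reaches 59.1 CPM in the double mutant, where replicate 2 stands at 8.58 CPM.

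The double mutant against WT measures both changes together. The MHC class Ib genes H2-Q7 and H2-Q6 (chromosome 17, from 35439155 to 35443773 and from 35424850 to 35430055) rose, H2-Q7 from 5.06 ± 1.76 to 40.7 ± 22.2 CPM (SD, n = 4 and 4; log2 fold change 3.01, SE 0.45, adjusted p = 0.026, edgeR quasi-likelihood test). H2-Q6 went from 1.49 to 19.8 CPM (3.74, SE 0.59, adjusted p = 0.026), and both are uncertain because they are near-identical copies whose reads the counting could split. Gng11 fell (-3.36, SE 0.48, adjusted p = 0.021), as did Tfpi2 (-3.34, SE 0.51, adjusted p = 0.026). Lipo3 fell as well (-1.15, SE 0.19, adjusted p = 0.044). Akr1c12, an aldo-keto reductase gene in a cluster of copies on chromosome 13 (4268176 to 4279433), fell from 15.6 to 2.54 CPM (-2.62, SE 0.45, adjusted p = 0.046) and is uncertain for the same reason as H2-Q7. Ptprc fell (-2.81, SE 0.24, adjusted p = 1e-04; lower in 4 of 4 libraries).

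In all, 13 genes passed (5 rose and 8 fell), with 954 at an unadjusted p under 0.05 where uniform p-values would give 605. Of these 13, 6 lay under the level set for named genes and were chosen after their values were seen. Vsig4 was at least 125-fold lower, taken against 3 counts over the group, and Dysf had 98 counts over WT and 1 over the double mutant, a ratio of 99.4 (95% counting interval 17.4 to 3960). Paqr9 fell (log2 fold change -4.98, SE 0.7), and Clec2f (3.67, SE 0.65), the adaptor gene Grap2 (2.82, SE 0.49) and the cytokine gene Il7 (1.83, SE 0.32) rose.

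Of the 11 lists that passed with the preset correlation, none did with an estimated one (adjusted p 0.71 to 0.81). Resorption genes stood lower in 16 of 16 members (median -0.79, camera adjusted p = 5.1e-09) with none passing adjusted over the list alone, and fusion and identity genes in 17 of 19 (median -0.73, adjusted p = 1.1e-06), of which Calcr fell (-2.44, SE 0.57, 0.014 adjusted over the list alone). Oxidative phosphorylation stood lower in 24 of 24 (median -0.43, adjusted p = 4e-06). MHC class II genes stood higher in 11 of 11 (median 1.53, adjusted p = 7.1e-05), and Cd80, Ciita and H2-DMb1 rose adjusted over the list alone. Inflammatory cytokine genes stood higher in 13 of 15 (median 1.93, adjusted p = 0.0011), glycolysis and hypoxia genes in 16 of 17 (median 0.38, adjusted p = 0.0077) and cell cycle genes in 24 of 24 (median 0.72, adjusted p = 0.023). Interferon response genes stood higher in 15 of 20 (median 0.5, adjusted p = 0.03) and NADPH oxidase and antioxidant genes in 15 of 17 (median 0.55, adjusted p = 0.03). None of the members of these last 5 lists or of oxidative phosphorylation passed adjusted over the list alone. The eosinophil markers Ear2 and Prg2 fell adjusted over the list alone (2 of 3 measured members, list adjusted p = 0.03), and Epor had 75 counts over WT and 1 over the double mutant (erythroid list adjusted p = 0.03). Outside the called lists, Socs2 fell (-1.93, SE 0.44, 0.007 adjusted over the list alone), and so did the macrophage receptor genes Cd163 (-4.51, SE 0.92) and Timd4 (-4.99, SE 1.09), each at 0.0029 adjusted over the list alone. With 1 progenitor marker, 4 genes outside the called lists fell that way, and 2 rose. The macrophage list had a positive median (0.22) while its test pointed down (adjusted p = 0.49). With 1 library left out, Ptprc kept its call in 8 of 8 fits, Gng11 and Paqr9 in 4, H2-Q7 in 3, Vsig4, H2-Q6 and Clec2f in 2, and the other 6 genes in 1. Without double-mutant replicate 3, 83 genes passed.

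The interaction compares the loss of Ptprc in FLT3 ITD cells with its loss in cells with normal Flt3. None of the 9 lists that passed with the preset correlation did with an estimated one (adjusted p 0.82 to 0.91). Resorption genes had a lower interaction term in 16 of 16 members (median log2 difference -1.45, camera adjusted p = 2.5e-07 with the preset correlation and 0.82 with an estimated one), and 6 passed adjusted over the list alone, Rab38 (-3.08, SE 0.94) and Snx10 (-2.03, SE 0.63) among them. Oxidative phosphorylation (24 of 24 negative, median -1.16, adjusted p = 4.9e-08) and fusion and identity genes (18 of 19 negative, median -0.97, adjusted p = 0.00024) went the same way. In the first none passed adjusted over the list alone, and in the second Calcr (-3.14, SE 0.79) and Itgb3 (-2.35, SE 0.67) did. Terms were higher for cell cycle genes (24 of 24, median 1.14, adjusted p = 1.5e-05), interferon response genes (19 of 20, median 0.73, adjusted p = 0.015), stromal markers (8 of 8, median 2.61, adjusted p = 0.036) and Src-family kinases and CD45 partners (10 of 12, median 0.61, adjusted p = 0.037). They were lower for neutrophil markers (8 of 10, median -3.2, adjusted p = 0.049) and for the mast cell and basophil markers Kit and Gata2 (2 of 2, median -2.06, adjusted p = 0.049), both of which passed adjusted over the list alone. No member of the cell cycle, interferon, stromal, Src-family or neutrophil list did. Outside the called lists, 4 genes were higher and 3 lower adjusted over the list alone. Over all genes, only Rbm44 passed (adjusted p = 0.031, edgeR quasi-likelihood test), with 2120 at an unadjusted p under 0.05 where uniform p-values would give 605. Rbm44 kept its call in 4 of 16 fits with 1 library left out. The size of its term is uncertain, because it had 1 count over the Ptprc KO group against 86 over WT (a ratio of 76.7, 95% counting interval 13.4 to 3070). Its level was low in Ptprc KO alone (0.0109 CPM, against 0.682 in WT, 0.391 in FLT3 ITD and 0.718 in the double mutant). A difference of the Ptprc KO cultures unrelated to Ptprc would give the same term, which was not tested. Without double-mutant replicate 3, 56 genes passed, and without FLT3 ITD replicate 4, 17 genes passed.

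Across all 12093 genes, which are not independent replicates, the log2 fold changes of FLT3 ITD with and without Ptprc had a Pearson r of 0.13 (Spearman rho -0.18, covariance 0.0495, same sign in 42.2%). The 2 comparisons share no library. Vsig4 and Paqr9 fell in both, where independent lists would share 0.0015 genes. The log2 fold changes of Ptprc loss with and without FLT3 ITD had an r of -0.36 (rho -0.57, covariance -0.0771, same sign in 28%). Ptprc alone fell in both, which its deletion in both comparisons fixed beforehand, so no other gene was shared.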

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

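The tests of gene position, of neutrophil or stromal cells of cells from a Ptprc-null line, and of splits with Ptprc not counted or with libraries summed were chosen only after the result was seen, as was the relation of the resorption score to all measures other than the macrophage score and the length trend.

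Of 220 checks of a library against the other 3 of its group, 29 found it far from them. Normally distributed values would give about 1 in 20 groups, or 11. The checks share libraries and are not independent, so the 29 do not measure an excess over chance. For Rbm44, Glrp1 and Dysf, with 1 count where the others had 0, the ratio could only be 1. FLT3 ITD replicate 4 accounts for many of the 29. On the first principal component it lay at 55.8 (the others -35.1 to -27.5). Its mean log2 CPM was 6.18 for repressors of osteoclast differentiation (others 4.24 to 4.44), 3.64 for STAT5 targets (2.46 to 2.51), 5.65 for ERK targets (3.92 to 3.98) and 4.06 for the cell cycle (6.05 to 6.09). It was 3.68 for inflammatory cytokines (1.01 to 1.36), 8.55 for NADPH oxidase and antioxidant genes (6.69 to 6.81), 0.11 for eosinophil markers (-1.81 to -1.75) and 4.35 for megakaryocyte markers (0.67 to 1.12), and Trip6 stood at 5.04 CPM (8.69 to 9.71).

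The spread of the osteoclast resorption score within groups came from FLT3 ITD replicate 4 at 8.89 (others 10.45 to 10.63) and double-mutant replicate 3 at 10.06 (others 8.13 to 8.45), among others. For neutrophils or stromal cells no conclusion can be drawn. S100a8 and Col1a1 reached at most 37.9 CPM in any library, but the level that a share of such cells would bring was not measured. The stromal score moved against the resorption score over the 16 libraries (deviations from group means, Pearson r -0.72, permutation p 0.0013, adjusted over 8 relations 0.0052, Spearman rho -0.79, p 0.00046, adjusted 0.0018, and r -0.66 without the 2 most extreme libraries). The neutrophil score had an r of -0.5 with it (permutation p 0.051, adjusted 0.082). A length trend is argued against, since its removal changed the pooled SD by 0.399%. Different shares of macrophage-like cells cannot be told apart from other causes, because their r of -0.56 (permutation p 0.022, adjusted 0.059; rho -0.45, p 0.081, adjusted 0.13) went to -0.29 without FLT3 ITD replicate 4 and Ptprc KO replicate 4. Differences in maturity at harvest or between animals may also play a part and stay untested, while oxidative phosphorylation moved with the resorption score (r 0.9, permutation p 1e-05, the smallest these permutations can give, adjusted 8e-05; rho 0.92; r 0.89 without the 2 most extreme libraries).

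Of the 100 genes with the lowest p in Ptprc KO against WT, Ptprc left out, 25 lay on chromosome 1 and 40 had another of them within 1 Mb, where 10000 random draws of 100 tested genes, a permutation test, had a median of 16 and at most 35 (p = 1e-04, the smallest these draws can give, and 0.017 to 0.96 in the other 5 comparisons). The draws take neighbouring genes as independent, whereas Ugt1a9, Ugt1a8 and Ugt1a6b among the 25 overlap each other and are not separate evidence. Chance placement of the genes on chromosome 1 cannot be told apart from a cause, because a permutation test by circular shifts along the genome put as many there with p = 0.039, between the bounds set for either answer, and the same shifts were void for neighbours (p = 0.74) because they keep the spacing of the genes, so random draws replaced them. A segment or regulation that comes with loss of Ptprc in both knockout lines is argued against as the cause for all 25, since in the double mutant against FLT3 ITD 16 of them had the same sign, 2 (Glrp1 and Ddx59) also an unadjusted p under 0.05, and the median change in the direction of the first comparison was 0.11 (SD 1.07) against 1.3 there, while a shared segment for part of them stays open. This argument is limited, because choosing the 25 for their low p raises the 1.3 whatever the cause. Changes over all genes were also wider in the second comparison (median absolute log2 fold change 0.352, against 0.103 in the first). The 4 dense regions, picked by eye after the positions were seen, were 85 to 92 Mb of chromosome 1 (8 of 49 tested genes), the surroundings of Ptprc on chromosome 1 (7 of 47), the part of chromosome 5 that holds Trip6 (5 of 43) and 3 to 15 Mb of chromosome 13 (9 of 35). Segments of another strain in the Ptprc KO line alone may be a candidate explanation, which needs reads and was not tested. The random draws gave their 0.017 for the double mutant against Ptprc KO. There chromosome 6 was the most frequent among the 100 genes with the lowest p, with 16 of them. The called genes Tfpi2, Gng11, Clec2f, Dysf and Gdf3 of that comparison lie on chromosome 6. Whether their position plays a part was not tested.

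Ptprc in FLT3 ITD replicate 2 lay under the other 3 FLT3 ITD libraries by a log2 difference of -0.98. Cells like those of the Ptprc-null libraries would need a share of 53.3 to 61.3% and are argued against, since genes at least 4 times higher in such a library than in every other FLT3 ITD library stayed under the level of that mixture, with median log2 ratios of -5.1 to -1.61 for the 5 Ptprc-null libraries with at least 3 such genes (a first test on 3 marker genes was void for part of the sources and was replaced). The library's dependence on transcript length is consistent with the low value: after removal of the length trend the difference was -0.22, a shrinkage of 77.7%, and Ptprc is a long gene (18313 nucleotides in the deposited table). In that library genes under 1000 nucleotides had a median log2 difference of 0.89 and the 689 genes over 12000 nucleotides one of -0.76. No biological explanation was tested.

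Other libraries far from their group were WT replicate 1 in its trend with gene length (rho 0.167, others 0.109 to 0.112) and FLT3 ITD replicate 2 in endothelial markers (-0.33, others 0.32 to 0.42). Ptprc KO replicate 4 stood at 3.52 for inflammatory cytokines (0.38 to 0.74) and 8.1 for NADPH oxidase and antioxidant genes (6.5 to 6.6), and Ptprc KO replicate 2 at 7.12 for glycolysis and hypoxia (6.63 to 6.68). Double-mutant replicate 2 stood at 3.63 for STAT5 targets (2.63 to 2.79) and 6.87 for MHC class II genes (4.43 to 4.6). In CPM, the single genes were Ptprc at 412 in WT replicate 2 (464 to 472), Vsig4 at 1.44 in Ptprc KO replicate 1 (3.29 to 3.85), Stard13 at 12.6 in Ptprc KO replicate 4 (3.15 to 3.44), H2-Q7 at 8.58 (45.3 to 59.1) and H2-Q6 at 3.56 (21.3 to 27.9) in double-mutant replicate 2, and Il7 at 0.275 in WT replicate 3 (0.64 to 0.663) and 1.16 in double-mutant replicate 1 (2.13 to 2.38). With 1 count where the others had 0, Rbm44 stood at 0.0438 in Ptprc KO replicate 2, Glrp1 at 0.0357 in Ptprc KO replicate 4 and Dysf at 0.0306 in double-mutant replicate 1.

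By a test of the interaction, the effect of losing Ptprc differed between FLT3 ITD and normal Flt3 for Rbm44 (log2 difference 6.54, uncertain in size because it rests on 1 count over the Ptprc KO group). Rbm44 starts at 91.1 Mb of chromosome 1, in the dense region of 85 to 92 Mb. It was low in Ptprc KO alone (0.0109 CPM, against 0.682 in WT and 0.718 in the double mutant). A difference of the Ptprc KO cultures unrelated to Ptprc cannot be told apart from an interaction there. Camera with a preset correlation called 9 lists for the interaction. The medians were -1.45 for resorption, -0.97 for fusion and identity, 0.61 for Src-family kinases and CD45 partners, 1.14 for the cell cycle, 0.73 for the interferon response, -1.16 for oxidative phosphorylation, -3.2 for neutrophil, -2.06 for mast cell and basophil and 2.61 for stromal markers, and none of these lists passed with an estimated correlation.

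Each pair of groups has 35 splits of its 8 libraries. Only the real split gave as many genes for FLT3 ITD against WT (1 of 35, real count 5, highest other 0). The same held for Ptprc KO against WT (1 of 35, real count 4, highest other 0) and the double mutant against WT (1 of 35, real count 13, highest other 0). Without the deleted Ptprc the counts of the last 2 were 3 and 12 (each 1 of 35, highest other 0). A share of 1 in 35 is the smallest these splits can give, and it was not adjusted over the comparisons. It argues against chance for these counts without excluding it, and the FLT3 ITD count was 0 without WT replicate 1 or 3. With FLT3 ITD replicates 1 and 3 summed, 1 of 35 splits of the 7 libraries gave as many genes for FLT3 ITD against WT (1, highest other 0), and the splits of 8 libraries took them as separate cultures. For the double mutant against FLT3 ITD, 4 of 35 splits gave as many genes (1, highest other 4411), which says nothing of the call itself, since the 1 gene was the deleted Ptprc, which kept its call in 8 of 8 fits with 1 library left out. Chance cannot be excluded for its DESeq2 count (3 of 35; 982, highest other 5132) or for the gene count of the double mutant against Ptprc KO (2 of 35; 11, highest other 3070). For the interaction 2 of 100 drawn splits gave as many genes (1, highest other 2975, and 0 in the remaining 98). These splits mix all 4 genotypes, so they test for no difference between groups at all, and whether chance gives the interaction itself is left open. The splits with the highest counts point to a structure of the samples: 4411 genes came from double-mutant replicates 1, 2 and 4 with FLT3 ITD replicate 4 against the rest, and 3070 from the same 3 with Ptprc KO replicate 4.

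For the lists, splits as large were common and chance cannot be excluded: 26 of 35 for FLT3 ITD against WT (5 lists, highest other 19), 26 of 35 for Ptprc KO against WT (8, highest other 20), 23 of 35 for the double mutant against FLT3 ITD (6, highest other 18), 27 of 35 against Ptprc KO (7, highest other 18), 13 of 35 against WT (11, highest other 19) and 43 of 100 for the interaction (9, highest other 20). The same holds for the correlations across genes: 88 of 100 splits gave an absolute r as large for the FLT3 ITD effect (0.128, highest other 0.786) and 35 of 100 for the Ptprc effect (-0.356 in the fit used for splits, highest other -0.806).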

How the results depend on the processing

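The fits with libraries summed, the length trend removed, 1 surrogate variable or the reads implied by the TPM table, and the permutation of lists, were chosen after seeing the data. Counts are given in the order FLT3 ITD against WT, Ptprc KO against WT, double mutant against FLT3 ITD, against Ptprc KO and against WT, and interaction, and start from 5, 4, 1, 11, 13 and 1 genes and 5, 8, 6, 7, 11 and 9 lists. Unless stated, the cause was not tested.

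Gene counts stayed within 1.5 times in all 6 with RLE factors and without a filter. With a mean count of at least 50, which tests fewer genes, they were 1, 2, 1, 3, 5 and 0. With only the 2 groups compared, which leaves fewer libraries for the spread, they were 0, 2, 0, 0 and 1 in the first 5. DESeq2 called 64, 12, 982, 340, 132 and 174. In simulated counts of genes drawn independently, unlike the real ones, it made 24 to 41 false calls per comparison beside 161 to 168 of 200 true changes. Voom with quality weights called 1898, 482, 6999, 6966, 3898 and 7283, with weights of 8.47 and 9.74 on the near-identical FLT3 ITD replicates 1 and 3. Limma on log2(TPM + 1) called 4, 2, 2, 15, 8 and 0, and shifted the median log2 fold change of all genes to -0.21 in FLT3 ITD against WT, 0.22 in the double mutant against FLT3 ITD and 0.31 in the interaction, from 0.04, 0.03 and 0.02. With FLT3 ITD replicates 1 and 3 summed, the counts for the same comparisons were 1, 1 and 0, and with replicate 2 left out as well 0, 1 and 0. Removing the length trend gave 2, 4, 3, 14, 12 and 1, 1 surrogate variable 49, 8, 3, 74, 78 and 1, and the reads implied by TPM values 4, 4, 1, 15, 6 and 0.

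The labels give the groups the same replicate numbers without saying that they pair. With the replicate block, the gene counts were 0, 1, 1, 47, 9 and 0, and the list counts stayed within 1.5 times. Deviations of same-numbered libraries correlated over 0.1 in 12 of 24 pairs of libraries (range -0.633 to 0.851, median 0.0745, against -0.009 for libraries with other numbers). Of the 16 libraries, 8 correlated best with their own number. These values leave a pairing open, and the main fit took none because the labels state none.

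List counts fell to 0 in all 6 with an estimated correlation and with fry, and to 0 in the 5 pairs of groups with exact permutation. For FLT3 ITD against WT they were 3 with a mean count of at least 50, 2 with replicates 1 and 3 summed, 11 with replicate 2 left out as well, and 8 with the length trend removed. For the double mutant against Ptprc KO they were 15 without a filter and 11 with only the 2 groups. The list medians of all called lists kept their sign as differences of mean log2 values, with TMM or RLE factors or with TPM.

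Leaving out each library in turn gave 0 to 3 genes and 1 to 9 lists for FLT3 ITD against WT, where every left-out library moved the gene count by over 1.5 times (0 without WT replicate 1 or 3, 3 without WT replicate 2 or FLT3 ITD replicate 4, and 1 otherwise) and the list count was 1 and 2 without FLT3 ITD replicates 1 and 3, 9 without replicate 2, and 8 without replicate 4 or WT replicate 3. For Ptprc KO against WT it gave 2 to 4 genes (2 without WT replicate 4) and 3 to 9 lists (3 without Ptprc KO replicate 2). For the double mutant against FLT3 ITD it gave 1 to 1798 genes (1798 without FLT3 ITD replicate 4, 1315 without double-mutant replicate 3, 2 without double-mutant replicate 2 or 4) and 5 to 7 lists. Against Ptprc KO it gave 2 to 786 genes (786 without double-mutant replicate 3, 2 and 4 without its replicates 1 and 4, 6 without Ptprc KO replicate 2 or 3) and 7 to 13 lists (13 without double-mutant replicate 4). Against WT it gave 1 to 83 genes (83 without double-mutant replicate 3, 1 without its replicate 1 or 4 or WT replicate 3, 4 without its replicate 2 or WT replicate 2, 3 and 5 without WT replicates 1 and 4) and 7 to 14 lists (7 without double-mutant replicate 3). The interaction gave 0 to 56 genes (56 without double-mutant replicate 3, 17 without FLT3 ITD replicate 4, 1 without Ptprc KO replicate 2 or FLT3 ITD replicate 3, and 0 otherwise) and 5 to 10 lists (5 without double-mutant replicate 3).

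Across genes, the correlation of the FLT3 ITD effect with and without Ptprc (0.128) was -0.044 with a mean count of at least 50 and ranged from -0.18 (without FLT3 ITD replicate 4) to 0.278 (without FLT3 ITD replicate 2) with 1 library left out. The correlation of the Ptprc KO effect with and without FLT3 ITD was -0.531 with a mean count of at least 50 and ranged from -0.455 to -0.086 (-0.086, -0.152 and -0.186 without Ptprc KO replicates 3 and 2 and WT replicate 3).

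Of the log2 fold changes of single genes under the alternatives, 3165 kept their direction and their side of the threshold, 244 no longer passed, 180 newly passed and 9 reversed, none of the reversed ones being a call. In Ptprc KO against WT these were Fdps at 0.08 without WT replicate 4 (-0.77 to 0.08 with each library left out), Cxcr2 at -0.62 with voom, and, without Ptprc KO replicate 4, Cd177 at -0.18 (-0.18 to 1.83) and Camp at -0.24 (-0.24 to 2.54). Ptprc in FLT3 ITD against WT was at 0.01 without FLT3 ITD replicate 2 (-0.36 to 0.01), 0.08 with that library left out and replicates 1 and 3 summed, and 0.07 with the length trend removed. Flt3, with 1 to 41 counts per library, was at 0.2 in FLT3 ITD against WT without WT replicate 1 (-0.77 to 0.2) and at -0.01 in Ptprc KO against WT without WT replicate 4 (-0.01 to 0.88), counts too low to show a change of that size. A covariate for sex was not run, because all 16 libraries had counts on Y-linked genes and the female marker is not in the tables, so the term could not be estimated.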

Other observations

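The genes described here were chosen after their values were seen, and no test was run on them as a set.

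Total counts over the 8 libraries with FLT3 ITD and the 8 without it, with or without Ptprc, are given here for 5 of the genes that were lower with FLT3 ITD. They are not the full set, which also holds Gdf3, Paqr9 and Dysf among others. Vsig4 had 0 counts against 691. Timd4, a receptor gene for phosphatidylserine, had 11 counts (0.0475 ± 0.0553 CPM, SD, n = 8) against 275 (1.26 ± 0.911 CPM, SD, n = 8), with ranges of 0 to 0.138 and 0.311 to 2.54 CPM. The ranges of the other 3 overlapped: Cd163, the haemoglobin scavenger receptor gene, had 44 and 347 counts (0 to 0.594 and 0.398 to 2.78 CPM), Ear2, an eosinophil-associated ribonuclease gene, 19 and 511 (0 to 0.624 and 0.38 to 5.22 CPM), and Epor 2 and 126 (0 to 0.0326 and 0 to 1.28 CPM). The macrophage list, fixed beforehand, passed in none of the comparisons for FLT3 ITD. Its median log2 fold change was -0.11 for FLT3 ITD against WT (7 of 15 positive, camera adjusted p = 0.1, pointing down), 0.22 for the double mutant against WT and 0.43 against Ptprc KO (10 of 15 positive in each). As differences of mean log2 CPM, which weigh single high libraries less, the medians were -0.57, 0.11 and 0.58.

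Akr1c12 stood at 15.6 ± 4.03 CPM in WT and at 2.27 ± 0.381 CPM in Ptprc KO, 4.75 ± 3.56 CPM in FLT3 ITD and 2.54 ± 1.1 CPM in the double mutant (SD, n = 4 each). It passed against WT for the double mutant (adjusted p = 0.0464), a call kept in 1 of 8 fits with 1 library left out, and missed the threshold for Ptprc KO (adjusted p = 0.0596), where 5 of the alternatives called it. Akr1c12 lies in the dense region of 3 to 15 Mb of chromosome 13 described above for Ptprc KO against WT. In FLT3 ITD against WT, chromosome 13 was the most frequent among the 100 genes with the lowest p (10 of them). Whether its position plays a part was not tested.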
